A study of Mus musculus with 4 samples.

How the data were processed

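RNA sequencing was done on endothelial cells sorted by flow cytometry from the brains of 4-week-old (postnatal day 28) C57BL/6 mice. Per the labels' protocols, brains of mice with an SP-A-Cre driver, a floxed Pten allele and a Cre-dependent EYFP reporter were digested, endothelial cells were sorted and total RNA was extracted. The protocol gives the animals without knockout as carrying 1 floxed and 1 intact Pten allele, whereas their genotype label reads wild type. They are called WT here, as their titles do, and the conditional knockout libraries are called PTEN-cKO. Each group holds 2 libraries. The labels do not say that the replicates came from separate animals, so the p-values measure only the spread between these samples, which can be technical.

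The authors deposited 1 table with a count and an FPKM value per library and a gene length for each of 63426 rows. The submitters' processing notes name the mm10 build, Bowtie, TopHat, HTSeq and DESeq2, without versions, roles or order. The gene annotation, the strand setting, whether a count is a read or a read pair and which Pten exons were deleted are not given in the sources used here. The deposited FPKM values equal the deposited counts times 1e+09, divided by the gene length and by the sum of the count column, within a relative difference of 1e-06 for all values above 50 counts.

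Of the rows, 17967 carry a gene identifier, and 17911 of these identifiers were found in a RefSeq gene table of the same mouse build, which gave the coordinates. The other 45459 rows are assembled loci without a gene name. They held 7.75% and 7.34% of the counts in WT replicates 1 and 2 and 7.44% and 6.99% in PTEN-cKO replicates 1 and 2, and were left out of library sizes and tests. The lowest and highest of these shares have 95% Wilson intervals of 6.98 to 7.00 and 7.74 to 7.75, which cover counting error only. Total counts were 39226484 and 36173793 in WT replicates 1 and 2 and 34807115 and 38441059 in PTEN-cKO replicates 1 and 2. The counts of the libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 43.1 for WT and 50.5 for PTEN-cKO, so every library was counted as 1 sample.

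Genes were tested on the deposited counts with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after filterByExpr (minimum count 10), TMM normalisation and a model with the group alone. The filter left 14438 genes. P-values were adjusted by Benjamini and Hochberg over these genes, with a threshold of 0.05. CPM values were computed here with TMM-normalised library sizes. Group values are means ± SD over 2 libraries, and fold changes are log2 PTEN-cKO over WT ± SE. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so single values were not tested in that way.

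Before the data were examined, 34 lists of genes for pathways, endothelial functions and cell types were fixed, and the 32 with at least 5 tested genes were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes. The p-values of the lists were adjusted over the 32 lists. Members were counted as past the threshold over all genes tested and adjusted over the list alone. The lists of sex-linked genes and of oligodendrocyte precursor markers had 4 and 3 tested genes and were not tested. The lists overlap in part. For example, 6 of 29 transporter genes, 7 of 23 arterial markers and 13 of 30 tip cell genes stand in another list as well. So do 9 of 17 venous and 11 of 22 common endothelial markers.

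The rule for the genes that the text names was also fixed beforehand. It takes Pten, the 12 largest rises and 12 largest falls past the threshold with a mean of at least 5 CPM and no overlap between the libraries of the groups, up to 4 members of each list with the smallest p, and Nedd4l, Mfsd2a, Cav1, Cldn5, Foxo1, Plvap and Slc2a1. Predicted or clone names, sex-linked genes and haemoglobins were left out of the largest rises and falls. Of the 157 genes that the rule gives, the text names a part, which was chosen for length after their values were seen.

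The alternatives were DESeq2 size factors in the edgeR fit, no filter beyond 1 count, a filter of CPM above 1 in 2 libraries, the Wald test of DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, each library left out in turn, and for the lists an estimated correlation and fry. With a library left out, the genes tested were kept, a choice made after the counts with the genes filtered anew had been seen, and the lone library of its group was assumed to vary like the other group. The fit of all rows with the assembled loci, the fits filtered anew, the edgeR setting legacy = FALSE and the counts of list members under each setting were added after seeing the data.

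The test was checked on simulated counts drawn for PTEN-cKO against WT with the means and library sizes of these libraries. Among the 14002 genes of that step, it recovered 53 of 95 genes changed by 1 on the log2 scale (55.8%) and 69 of 97 changed by 2 (71.1%), with 7 false calls. Among genes above the median expression it recovered 46 of 55 and 48 of 48. The simulated dispersions followed the fitted trend without spread between genes. Figures were drawn with matplotlib 3.10.9.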

Results

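Gene expression was measured by RNA sequencing in brain endothelial cells sorted from 4-week-old mice, with 2 WT libraries and 2 libraries labelled PTEN-cKO. PTEN is the lipid phosphatase that opposes PI3K and AKT signalling, and the design asks which genes and pathways it regulates in the endothelium of the brain at this age. Between 32218641 and 36188280 counts per library fell on rows with a gene identifier. Markers common to endothelial cells, such as Cldn5, Pecam1 and Cdh5, summed to 35604 ± 2170 CPM (mean ± SD, n = 2 here and below) in WT and 34661 ± 2981 CPM in the libraries labelled PTEN-cKO, whereas neuron markers summed to 49.0 and 61.5 CPM. RNA of other cells was present as well, with 1253 to 4563 CPM for choroid plexus and ependymal markers, 874 to 4847 CPM for erythroid markers and 881 to 2235 CPM for pericyte markers per library.

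The targeted gene was examined first. Pten (gene identifier 19211, chromosome 19, 32757577 to 32826160, mm10) had 2364 and 2213 counts in the WT libraries and 2426 and 2474 counts in the libraries labelled PTEN-cKO. These are 66.5 ± 1.08 and 71.5 ± 5.59 CPM. The log2 fold change was 0.10 ± 0.12 (adjusted p = 0.882, edgeR quasi-likelihood test), with a 95% interval from -0.18 to 0.38. The gene-level count of Pten was thus not lower in the libraries labelled PTEN-cKO and does not check their labels, and all directions below follow the labels as given. The gene row covers 8212 bases, of which the last exon of the longest annotated transcript holds 6318, and counts per exon were not used here.

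In the libraries labelled PTEN-cKO, 45 of 14438 genes passed the threshold, of which 22 rose and 23 fell. The strongest rise among the named genes was that of Igfbp5, a secreted binding protein of insulin-like growth factors (16011, chromosome 1, 72858065 to 72874865), from 4.32 ± 0.0123 to 41.5 ± 10.1 CPM (9.60-fold, log2 3.26 ± 0.24, adjusted p = 0.0128). The strongest fall was that of Islr2, a membrane protein with immunoglobulin and leucine-rich repeat domains (320563, chromosome 9, 58196297 to 58204319), from 63.8 ± 8.21 to 3.63 ± 0.0771 CPM (17.6-fold, log2 -4.13 ± 0.19, adjusted p = 0.00225). Slc1a3, the glutamate transporter GLAST (20512, chromosome 15, 8634124 to 8710807), rose from 20.6 ± 1.29 to 111 ± 12.6 CPM (log2 2.43 ± 0.14, adjusted p = 0.00508). G6pc, the catalytic subunit of glucose-6-phosphatase (14377, chromosome 11, 101367716 to 101377903), fell from 10.8 ± 0.822 to 0.880 ± 0.145 CPM (log2 -3.61 ± 0.39, adjusted p = 0.0303).

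**Figure D1:**
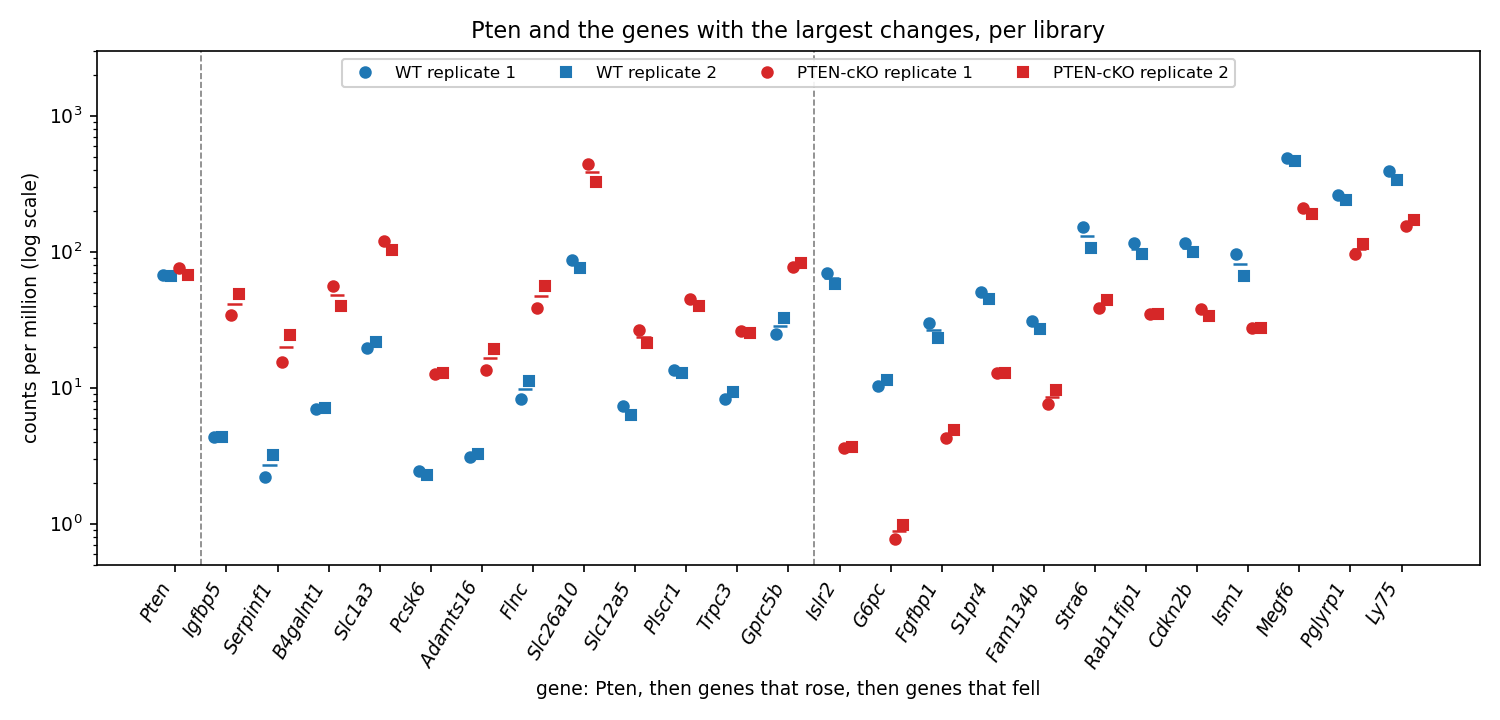
CPM on a log axis for Pten, the 12 genes with the largest rises and the 12 with the largest falls, with circles and squares for replicates 1 and 2, blue for WT, red for PTEN-cKO and short lines for the group means. Pten lies at 66.5 and 71.5 CPM on average, Igfbp5 moves from 4.32 to 41.5 CPM and Islr2 from 63.8 to 3.63 CPM. That the libraries of the groups do not overlap was required of the 24 called genes.

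Among the other rises, Serpinf1, which encodes the secreted factor PEDF, changed by 2.88 ± 0.35 on the log2 scale. The ganglioside synthase gene B4galnt1 rose by 2.77 ± 0.22 and Slc26a10 by 2.23 ± 0.17, to 383 ± 77.5 CPM. These neighbours on chromosome 10 (B4galnt1 127165156 to 127172340, Slc26a10 127171393 to 127180705) overlap by 948 bases, and since the strand setting is not given, reads of the one cannot be told from reads of the other in the overlap. Pcsk6, a proprotein convertase gene, rose by 2.42 ± 0.32, the metalloprotease gene Adamts16 by 2.38 ± 0.31 and the filamin gene Flnc by 2.27 ± 0.26. Slc12a5, which encodes the potassium-chloride cotransporter KCC2, rose by 1.80 ± 0.24, the phospholipid scramblase gene Plscr1 by 1.68 ± 0.17, the cation channel gene Trpc3 by 1.54 ± 0.20 and the receptor gene Gprc5b by 1.47 ± 0.16. Whether these rises came from endothelial cells was not tested. In the same libraries pericyte (median 0.78) and smooth muscle markers (median 0.91) were higher.

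Among the other falls, Fgfbp1, which encodes a carrier of fibroblast growth factors, changed by -2.52 ± 0.24 and the sphingosine-1-phosphate receptor gene S1pr4 by -1.89 ± 0.17. Stra6, the receptor for retinol-binding protein (chromosome 9, 58063793 to 58154004), fell from 129 ± 32.6 to 41.3 ± 4.11 CPM (log2 -1.65 ± 0.19). It lies 42.3 kb from Islr2. Fam134b, a receptor for autophagy of the endoplasmic reticulum, changed by -1.75 ± 0.22, the endosomal recycling gene Rab11fip1 by -1.60 ± 0.13 and the cyclin-dependent kinase inhibitor gene Cdkn2b by -1.59 ± 0.14. Ism1 changed by -1.57 ± 0.20, Megf6 by -1.26 ± 0.11, Pglyrp1 by -1.25 ± 0.12 and the endocytic receptor gene Ly75 by -1.16 ± 0.12.

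The number of called genes depended on single libraries. It was 3 without WT replicate 1, all among the 45, 9 without PTEN-cKO replicate 2 (6 among the 45), 52 without WT replicate 2 (29) and 39 without PTEN-cKO replicate 1 (15), and Slc1a3 and Islr2 were past the threshold without each of the 4 libraries. With the genes filtered anew in the 3 libraries it was, in the same order, 7, 42, 67 and 125 (6, 30, 32 and 38 among the 45). The count was 736 with the replicate number as a block and 452 with DESeq2. It was 565 without a low-count filter (344 rose, 60.9%, against 48.9% of the 45) and 25 with the assembled loci in the fit. With limma on FPKM it was 14 (64.3% rose) or 0, with a pseudocount of 0.1 or 1.

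FOXO transcription factors are restrained by AKT, and of 37 tested FOXO target genes 2 fell and none rose over all genes tested. These were G6pc and Angpt2, the TIE2 ligand angiopoietin-2, which went from 161 ± 11 to 77.9 ± 5.66 CPM (log2 -1.05 ± 0.12, adjusted p = 0.0309). Adjusted over the list alone, 5 fell (2 or 3 passed without any 1 library), among them the PI3K inhibitor gene Pik3ip1 (log2 -0.69 ± 0.14) and the autophagy gene Gabarapl1 (log2 -0.51 ± 0.10). As a list they were called as lower by camera (adjusted p = 0.00938), but not with an estimated correlation (adjusted p = 0.790) or without PTEN-cKO replicate 1 (adjusted p = 0.167). Of the members, 17 lay above 0 and 20 below, with a median of -0.05 and a mean of -0.13, and of the 11 with an unadjusted p below 0.05, 3 rose. Without WT replicate 1 the mean was 0.05. Of 31 components of PI3K and AKT signalling, none passed over all genes. The genes Sgk1 (log2 0.82 ± 0.12) and Pik3r3 (1.01 ± 0.16) rose and Igf1r (-0.62 ± 0.14) and Akt3 (-0.66 ± 0.16) fell adjusted over the list alone (2 passed without PTEN-cKO replicate 2), and the list was not called (adjusted p = 0.885). Foxo1 had a log2 fold change of -0.14 ± 0.15 (adjusted p = 0.874) and the ubiquitin ligase gene Nedd4l 0.17 ± 0.12 (adjusted p = 0.736).

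Transporters of the blood-brain barrier were lower in the libraries labelled PTEN-cKO, in which pericyte (median 0.78) and smooth muscle markers (median 0.91) were higher. Of 29 tested genes, 25 lay below 0, with a median log2 fold change of -0.39, and their CPM summed to 45182 ± 4599 in WT and 34408 ± 2304 in PTEN-cKO. Over all genes, 2 fell, the carbonic anhydrase gene Car4 (log2 -1.13 ± 0.14, adjusted p = 0.0449) and the glutamine transporter gene Slc38a5 (-0.80 ± 0.10, adjusted p = 0.0474). Adjusted over the list alone, 12 fell and 1 rose (5 past the threshold without PTEN-cKO replicate 2 and 3 without WT replicate 1). The 12 included the large neutral amino acid transporter genes Slc7a5 (-0.87 ± 0.14) and Slc3a2 (-0.54 ± 0.12), the cationic amino acid transporter gene Slc7a1 (-0.58 ± 0.13), the lipid flippase gene Atp10a (-0.72 ± 0.12) and the lipid transporter gene Mfsd2a (-0.48 ± 0.15, adjusted p over all genes 0.363). The glucose transporter gene Slc2a1 went from 10541 ± 226 to 8508 ± 869 CPM (-0.31 ± 0.14, adjusted p = 0.560). The list was called by camera (adjusted p = 1.92e-15), also without each library, and not with an estimated correlation (adjusted p = 0.790).

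Other parts of the barrier programme were not called by camera with all libraries. Of 20 junction genes none passed (list adjusted p = 0.665), and Cldn5, the main claudin of the barrier, had 8271 ± 112 CPM in WT and 8587 ± 778 CPM in PTEN-cKO (log2 0.05 ± 0.14, adjusted p = 0.958). The values were -0.36 ± 0.12 for Ocln and 0.64 ± 0.23 for Jam3. Of 20 genes of caveolae and transcytosis, none passed over all genes. Cav1 rose (0.62 ± 0.12) and Sdpr fell (-0.47 ± 0.11) adjusted over the list alone, where 0 or 1 passed without any 1 library, and the list was not called (adjusted p = 0.752). Plvap, a marker of fenestrated endothelium, was at 32.0 ± 7.72 and 19 ± 7.09 CPM (-0.75 ± 0.30, adjusted p = 0.483). Of 21 targets and receptors of Wnt and beta-catenin, which maintain the barrier, 1 fell adjusted over the list alone, the Wnt deacylase gene Notum (-0.90 ± 0.17; 0 passed without WT replicate 1 or PTEN-cKO replicate 2), and the list was not called (adjusted p = 0.104), though it was as lower without WT replicate 2 (0.00560) and PTEN-cKO replicate 1 (0.0261). Of the 21, 9 lay above 0, with a median of -0.02. The values were -0.45 ± 0.13 for Apcdd1, -0.45 ± 0.11 for Lrp5 and 0.42 ± 0.12 for Tnfrsf19, all not past the threshold. Of 22 markers common to endothelial cells none passed (list adjusted p = 0.104, and called as lower without WT replicate 2 and PTEN-cKO replicate 1, with 0.00229 and 0.00558), with 9 above 0, a median of -0.02, Robo4 at -0.75 ± 0.16, Emcn at -0.60 ± 0.15 and Ly6a at 0.22 ± 0.11.

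**Figure D2:**
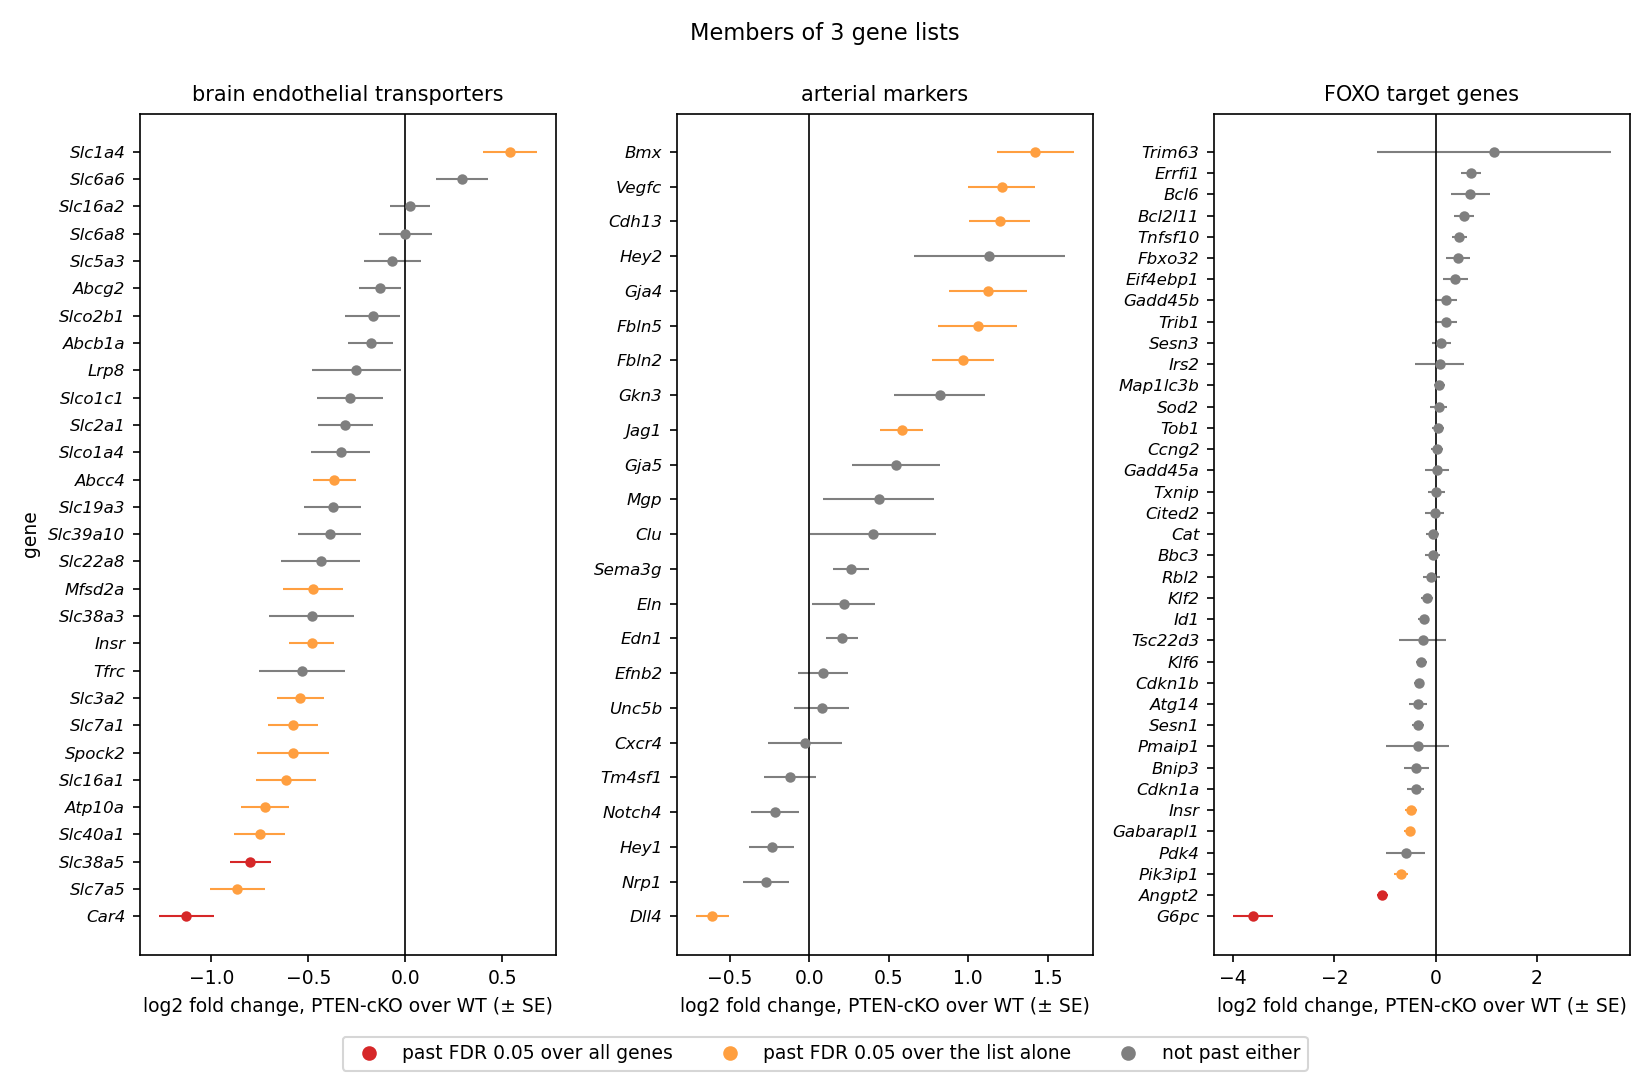
Log2 fold change of PTEN-cKO over WT, with SE bars, for the tested members of the transporter, arterial and FOXO target lists, sorted by value, with red for genes past the threshold over all genes, orange for genes past it over the list alone and grey for the rest. Of the transporters, 25 of 29 lie below 0, and of the arterial markers 17 of 23 lie above 0.

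Arterial markers were higher as a list (camera adjusted p = 3.46e-06, also called without each library). With an estimated correlation the call was not held (adjusted p = 0.790). Of 23 genes, 17 lay above 0, with a median of 0.40, and none passed over all genes. There were 7 that rose and 1 that fell adjusted over the list alone. The 7 included the tyrosine kinase gene Bmx (log2 1.42 ± 0.24), the lymphangiogenic growth factor gene Vegfc (1.21 ± 0.21) and the cadherin gene Cdh13 (1.2 ± 0.19), and the 1 was the Notch ligand gene Dll4 (-0.61 ± 0.10). Smooth muscle and pericyte markers were higher in the same libraries, as given below. Of 17 venous markers, 1 fell (Slc38a5, also the 1 gene past the threshold adjusted over the list alone, where 11 passed without PTEN-cKO replicate 1), while the list was called as higher (adjusted p = 0.0121, and 0.80 with an estimated correlation). That call rested on PTEN-cKO replicate 2, where the list summed to 11169 CPM against 6316 to 7097 CPM in the other libraries, and without it the mean was -0.28 (adjusted p = 0.819). Vwf was at 3835 ± 148 and 6142 ± 2317 CPM, and the venous regulator Nr2f2 at 14.9 ± 1.87 and 25.2 ± 4.18 CPM (log2 0.76 ± 0.21), both not past the threshold.

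Of 30 genes of tip cells and angiogenesis, 1 rose (Trp53i11, log2 1.06 ± 0.12, adjusted p = 0.0311) and 1 fell (Angpt2). Adjusted over the list alone, 8 rose, among them the matrix metalloprotease gene Mmp14 (1.58 ± 0.22) and the laminin gene Lamb1 (0.77 ± 0.12), and 3 fell, Dll4 among them (7 passed without WT replicate 1). The list was called as higher (adjusted p = 0.0327), although its median was 0.00. With an estimated correlation the adjusted p was 0.856, and without WT replicate 2 and PTEN-cKO replicate 1 it was 0.692 and 0.227. Of 34 secreted factors, 1 fell over all genes, Angpt2. Adjusted over the list alone, 7 rose, with Vegfc and the midkine gene Mdk (1.66 ± 0.33) among them, and 3 fell, with Edn3 (-0.50 ± 0.10). Without WT replicate 1 or PTEN-cKO replicate 1, 4 passed in that way, and 6 without PTEN-cKO replicate 2. The list was called as higher (adjusted p = 0.00392, also without each library) and not with an estimated correlation (adjusted p = 0.790). Pericyte (median 0.78) and smooth muscle markers (median 0.91) were higher in the same libraries as the tip cell and secreted factor lists. Genes of the TGF-beta and BMP response gave no call (20 genes, list adjusted p = 0.752). Their values included -0.47 ± 0.13 for Eng and 1.27 ± 0.43 for Bmp6. Their median was 0.01 and camera's direction was down.

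Of the metabolic lists, 1 was called. Of 17 genes of fatty acid synthesis none passed over all genes and 2 rose adjusted over the list alone, the desaturase gene Scd2 (0.47 ± 0.11) and the fatty acid synthase gene Fasn (0.65 ± 0.15). The list was called as higher (adjusted p = 0.0310, and 0.790 with an estimated correlation), and 2 members passed in all libraries but none without WT replicate 1 or either PTEN-cKO library. The list call was lost without any 1 of the 4 libraries (adjusted p from 0.0541 to 0.0998). Of 25 cholesterol synthesis genes none passed (list adjusted p = 0.397, 9 above 0, Dhcr24 at -0.37 ± 0.11), nor did any of 19 glycolysis genes (0.718, 10 above 0, Slc16a3 at 1.08 ± 0.34 and Pfkp at -0.25 ± 0.11), 32 genes of oxidative phosphorylation (0.326, 11 above 0, Ndufa1 at -0.51 ± 0.14) or 34 cell cycle genes (0.136, 13 above 0, Rrm2 at -1.47 ± 0.40 and Mcm6 at -0.88 ± 0.25). Without WT replicate 1, oxidative phosphorylation (0.0150) and cell cycle (0.00410) were called as lower. Of 33 genes of the ATF4 and amino acid response none passed over all genes, and adjusted over the list alone 1 rose (Stc2, 1.71 ± 0.29) and 3 fell, the transporter genes Slc7a5, Slc3a2 and Slc7a1 given above (0 passed without WT replicate 1 or PTEN-cKO replicate 2). That list was not called (adjusted p = 0.793).

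Endothelial inflammation genes were called as higher (23 genes, median 1.5, camera adjusted p = 5.70e-07, and 0.790 with an estimated correlation), but none passed over all genes or adjusted over the list alone (16 did the latter without PTEN-cKO replicate 1). The list summed to 3208 CPM in PTEN-cKO replicate 2 and to 1533 CPM in PTEN-cKO replicate 1, beside 1446 and 1649 CPM in WT. Without PTEN-cKO replicate 2 the mean was -0.27. Icam1, Vcam1, Selp, Lcn2, Ackr1, Lrg1 and Il1r1 stand in the venous list as well, so the calls of these lists rest partly on the same genes. Leukocyte markers were highest in PTEN-cKO replicate 2 as well, with 56.8 CPM, beside 4.91 CPM in PTEN-cKO replicate 1 and 8.59 and 17.5 CPM in WT. Tnfaip3 was at 74.6 ± 2.93 and 148 ± 60.1 CPM, Ptgs2 at 21.9 ± 4.28 and 103 ± 102 CPM, and Cxcl2 at 3.07 ± 0.605 and 12.4 ± 8.21 CPM. Of 32 interferon response genes none passed over all genes or adjusted over the list alone (21 did the latter without WT replicate 2 and 12 without PTEN-cKO replicate 2), while the list was called as higher (median 0.43, adjusted p = 6.88e-07, and 0.856 with an estimated correlation). Without WT replicate 1 and PTEN-cKO replicate 1 its adjusted p was 0.277 and 0.227. Rsad2 was at 41.4 ± 26.0 and 87.3 ± 22.8 CPM and Mx1 at 2.56 ± 2.22 and 12.3 ± 6.74 CPM. Immediate early and dissociation genes, a sign of tissue handling, were called as higher as well (21 genes, none past either threshold with all libraries and 5 over the list alone without PTEN-cKO replicate 1, median 0.16, adjusted p = 0.0198, and 0.856 with an estimated correlation). Without WT replicate 1 and PTEN-cKO replicate 2 the adjusted p was 0.236 and 0.989, and Egr2 was at 5.47 ± 0.660 and 10.6 ± 3.24 CPM.

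Markers of mural cells were higher in the libraries labelled PTEN-cKO. Pericyte markers summed to 881 and 1352 CPM in WT and to 1411 and 2235 CPM in PTEN-cKO, and all 12 lay above 0. None passed over all genes, and 3 rose adjusted over the list alone, Atp13a5 (log2 1.55 ± 0.24), Vtn (1.11 ± 0.30) and Cspg4 (1.01 ± 0.28), while 1 marker passed in that way without PTEN-cKO replicate 2 or without WT replicate 1, 7 without PTEN-cKO replicate 1 and 10 without WT replicate 2. The list was called (adjusted p = 9.28e-08, also without each library, and 0.790 with an estimated correlation). Smooth muscle markers summed to 600 and 977 CPM in WT and to 1066 and 1849 CPM in PTEN-cKO (9 genes, none past either threshold with all libraries and 5 past that over the list alone without PTEN-cKO replicate 1 or WT replicate 2, adjusted p = 3.40e-05, also without each library, and 0.790 with an estimated correlation), with Acta2 at 0.96 ± 0.28 and Myh11 at 0.94 ± 0.31. Fibroblast markers were called as higher (9 genes, adjusted p = 0.00392, 0.790 with an estimated correlation and 0.179 without WT replicate 1; without PTEN-cKO replicate 2 the mean was -0.22, against 0.98 with all libraries), and 1 rose adjusted over the list alone, Ogn (2.17 ± 0.49, at 1.10 and 4.97 CPM; 0 without WT replicate 1 and 6 without WT replicate 2).

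Of 14 astrocyte markers, 1 rose over all genes, Slc1a3. In all 3 rose adjusted over the list alone, with Slc1a2 (0.82 ± 0.24) and Fgfr3 (0.51 ± 0.14) beside it, and the gap junction gene Gja1 fell (-0.67 ± 0.11), with 2 past that threshold without WT replicate 1 or PTEN-cKO replicate 2. The list was called as higher (adjusted p = 0.00392, and 0.790 with an estimated correlation). Without WT replicate 1 and PTEN-cKO replicate 2 its adjusted p was 0.179 and 0.228, and without the latter the mean was -0.46, against 0.38 with all libraries. Erythroid markers were called as lower (6 genes, none past either threshold with all libraries and 5 and 4 over the list alone without WT replicate 1 and PTEN-cKO replicate 2, 3817 ± 1457 against 1658 ± 1110 CPM, adjusted p = 0.00227, and 0.790 with an estimated correlation). Without WT replicate 2 and PTEN-cKO replicate 1 the adjusted p was 0.333 and 0.10. Hba-a1 had a log2 fold change of -1.28 ± 0.36 and Hbb-bs of -1.25 ± 0.49, and reads of both can be shared with near-identical copies.

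Lists for other cells gave no call with all libraries, where none of their members passed over all genes or over the list alone. Choroid plexus and ependymal markers summed to 1750 and 4563 CPM in WT and to 1253 and 3314 CPM in PTEN-cKO (9 genes, adjusted p = 0.0763), and microglia markers to 93.5 and 401 CPM and to 166 and 424 CPM (15 genes, adjusted p = 0.138). For both lists the libraries of a group differed by more than the group means. The adjusted p was 0.142 for perivascular macrophages (7 genes), 0.328 for leukocytes (7 genes), 0.863 for oligodendrocytes (9 genes) and 0.885 for neurons (11 genes, median 0.29, mean -0.08, camera direction down). Without 1 library some were called. Choroid plexus markers were lower without WT replicate 1 (6.38e-06) and PTEN-cKO replicate 2 (1.27e-07). Microglia markers were lower without WT replicate 1 (0.0416) and higher without WT replicate 2 (1.12e-09) and PTEN-cKO replicate 1 (0.000169), perivascular macrophage markers higher without WT replicate 2 (0.000176) and PTEN-cKO replicate 1 (0.00626), and leukocyte markers higher without PTEN-cKO replicate 1 (0.000231). The 3 tested oligodendrocyte precursor markers summed to 142 ± 10.5 and 118 ± 6.97 CPM. Most of this was Gpr17, at 131 ± 8.91 and 107 ± 13.9 CPM, while Sox10 was at 0.967 and 0.421 CPM on average. The 4 tested sex-linked genes, Eif2s3y, Ddx3y, Kdm5d and Uty, all lie on chromosome Y. They summed to 145 and 143 CPM in WT and to 70.9 and 172 CPM in PTEN-cKO, and each was lowest in PTEN-cKO replicate 1. Ddx3y was at 79.6 and 78.7 CPM in WT and at 41.3 and 90.6 CPM in PTEN-cKO. Whether the libraries differ in the sex of the animals was not tested.

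**Figure D3:**
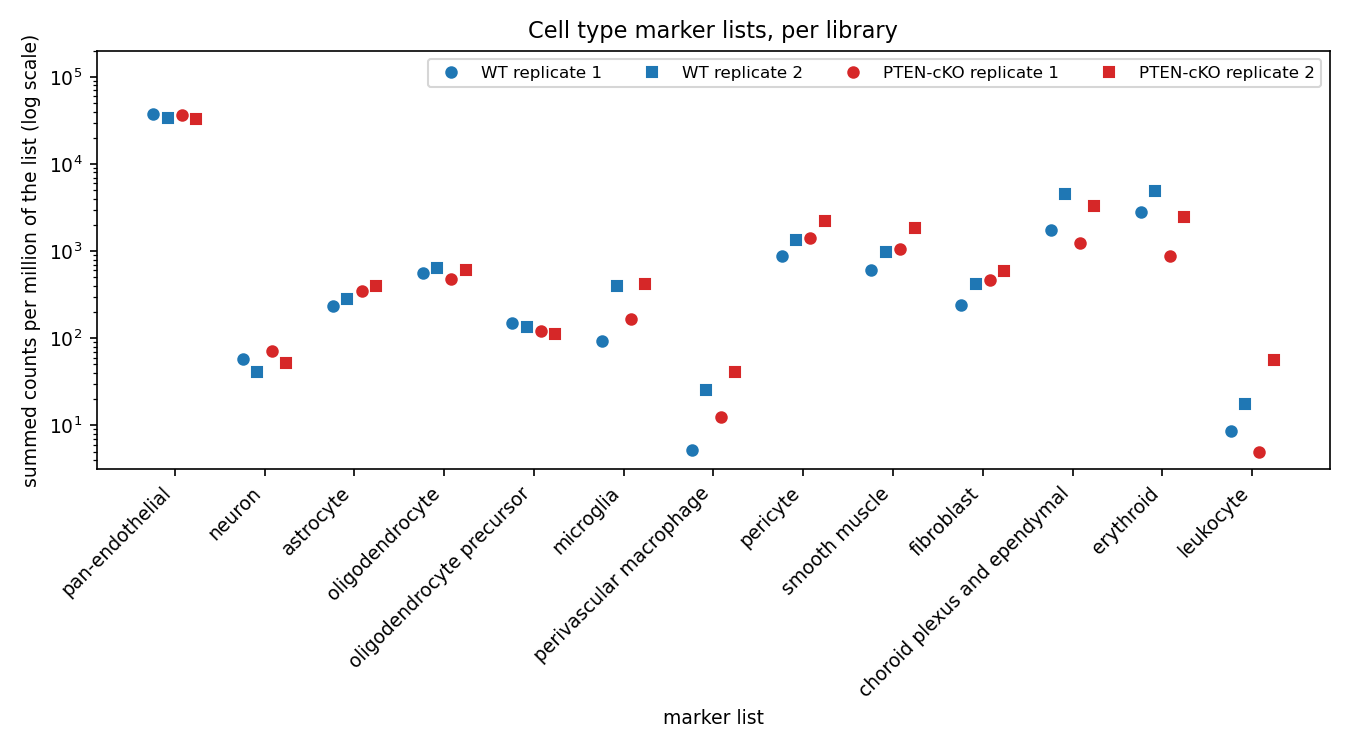
Summed CPM of each cell type marker list on a log axis, with circles and squares for replicates 1 and 2, blue for WT and red for PTEN-cKO. Common endothelial markers lie between 32553 and 37139 CPM in the 4 libraries and pericyte markers between 881 and 2235 CPM. Apart from neuron and oligodendrocyte precursor markers, all lists of other cells are higher in replicate 2 than in replicate 1 of both groups. Pericyte and smooth muscle markers are among them.

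With camera's preset correlation of 0.01, 15 of 32 lists were called, 12 higher and 3 lower. Of these, 5 were called in all 4 fits without 1 library. The estimated correlation was 0.50 for transporters, 0.91 for pericyte and 0.74 for smooth muscle markers, 0.80 for interferon and 0.58 for inflammation genes. Among called lists it was lowest for fatty acid synthesis (-0.058), FOXO targets (0.035), secreted factors (0.038) and arterial markers (0.095). Where it is high, the preset treats genes that vary together as nearly independent, so the small p-values do not establish a shift. None of the 32 was called with an estimated correlation (0 at an unadjusted p below 0.05). That setting rests on 2 residual degrees of freedom, and fatty acid synthesis lost its call although its estimate lay below the preset. The lost calls thus do not all come from a higher correlation, and with so few libraries they cannot exclude a shift. Fry, which tests whether a list moves one way on balance, called none either (smallest adjusted p 0.117), while its test for change in either direction called 7. These were FOXO targets (adjusted p = 2.46e-05), caveolae and transcytosis, tip cell genes and astrocyte markers (0.0115 each), secreted factors (0.0384), and PI3K and AKT components and Wnt and beta-catenin targets (0.0496 each), so that 3 of them, caveolae, Wnt and PI3K, were not called by camera.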

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

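The fit of all rows, the edgeR setting legacy = FALSE, the genes kept for the fits without 1 library and the counts of list members under each setting were chosen after seeing the data. The number of genes past the threshold was 45 with DESeq2 size factors, 60 with a filter of CPM above 1, 58 with limma-voom (39 of the 45 among them) and 63 with legacy = FALSE. It was 565 without a low-count filter and 452 with DESeq2, and both held all of the 45. It was 14 with limma on log2(FPKM + 0.1), 12 of them among the 45, and 0 with log2(FPKM + 1), where 1434 genes had an unadjusted p below 0.05. With the assembled loci in the fit it was 25, with 33637 rows tested. Without 1 library it lay between 3 (without WT replicate 1) and 52 (without WT replicate 2, 29 of them among the 45), with 39 without PTEN-cKO replicate 1 (15 among the 45) and 9 without PTEN-cKO replicate 2. With the genes filtered anew in the 3 libraries, which left 14995 to 15339 genes, the number differed from that with the genes kept, as given above. The number without 1 library thus depends on the filter as well as on the library, and it was not lower in every case. Apart from the fewer libraries and the larger number of rows tested, the cause of these shifts was not tested. With 3 libraries 1 residual degree of freedom is left.

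Replicates share a number across the groups, but no label ties a number to a litter, day or batch. Whether the numbers make 2 pairs of libraries is thus not known, and the main fit did not use them. With the replicate block, 736 genes passed (45 of the 45 among them) and 19 lists were called. Same-numbered libraries deviated together, with a correlation across genes of 0.18 over all tested genes and 0.39 at a mean of at least 5 CPM, and the first principal component (38.6% of the variance) separated the numbers.

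Pten stayed above 0 and past no threshold under all alternatives, with log2 fold changes from 0.02 to 0.18. All named genes past the threshold kept their direction under each alternative. Among uncalled results, Cldn5 changed sign, with values from -0.041 to 0.14 without 1 library.

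The number of called lists was 15 with DESeq2 size factors and without a filter and between 11 and 16 without 1 library. It was 0 with fry, which tests another hypothesis. It was also 0 with an estimated correlation, which rests on 2 residual degrees of freedom and so cannot exclude a shift. Without 1 library, camera's direction turned for these lists, given with the lowest and highest mean log2 fold change over the 4 fits. They were PI3K-AKT signalling components 0.0012 to 0.072, ATF4 and amino acid response 0.039 to 0.22, glycolysis -0.15 to 0.32, oxidative phosphorylation -0.14 to 0.066, endothelial junctions -0.037 to 0.013, venous -0.28 to 1.18, TGF-beta and BMP response -0.051 to 0.11, immediate early and dissociation genes -0.020 to 0.47, neuron -0.61 to 0.037, oligodendrocyte -0.15 to 0.91, microglia -0.54 to 2.17, perivascular macrophage -0.38 to 3.12, choroid plexus and ependymal -2.60 to 0.67 and leukocyte -1.37 to 2.30. Neuron markers also turned without a low-count filter (0.28). Of these, the venous and immediate early lists were called with all libraries. The mean changed sign while camera's direction did not in 4 called lists, FOXO targets (0.050 without WT replicate 1) and, without PTEN-cKO replicate 2, endothelial inflammation (-0.27), astrocyte (-0.46) and fibroblast markers (-0.22, still past the threshold as higher). In 5 uncalled lists it did so too, cholesterol synthesis, cell cycle, caveolae, Wnt and common endothelial markers. The cause was not tested, but in the venous list PTEN-cKO replicate 2 stands apart. Microglia markers passed the threshold as lower without WT replicate 1 and as higher without WT replicate 2.

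Depth was not varied, so what it limits was not tested. The median SE at a mean of at least 5 CPM, which holds counting error and the spread between libraries, was 0.17 on the log2 scale. The smallest called change was 0.80.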

Other observations

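The tests of the label swap, of the lower endothelial share, of dilution, of the arterial share and of the other astrocyte markers were chosen after the results were seen, as were the 100 kb of the neighbour test and the bound for the arterial share. Several genes past the threshold fell outside the rule for named genes and were chosen here after their values were seen. Fcgrt, the neonatal Fc receptor, fell from 1330 ± 96.1 to 664 ± 64.9 CPM (log2 -1.0 ± 0.13). Tbc1d4, a substrate of AKT that controls glucose transporter traffic, fell from 468 ± 41.3 to 225 ± 2.60 CPM (log2 -1.06 ± 0.11). The polyamine oxidase gene Smox fell (-0.85 ± 0.11), and Amd1, whose product supplies the aminopropyl groups of polyamines, rose (1.2 ± 0.15). The monoacylglycerol lipase gene Mgll (-1.15 ± 0.11) and the copper transporter gene Slc31a1 (-1.03 ± 0.10) fell. Adh1, an alcohol and retinol dehydrogenase gene, rose (1.39 ± 0.18), as did the carbonic anhydrase gene Car14 (1.37 ± 0.14). All 8 lost their call without at least 1 library, with the genes tested kept.

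Hbb-y, an embryonic globin gene, rose from 1.81 ± 0.466 to 24.9 ± 5.66 CPM (log2 3.78 ± 0.32), while the adult globins Hba-a1 and Hbb-bs lay below 0, and its reads can be shared with other globin genes. E030002O03Rik, which lies 299.8 kb from it on chromosome 7, rose from 15.5 ± 2.46 to 98.6 ± 9.79 CPM (log2 2.67 ± 0.17, adjusted p = 0.00580) and was past the threshold without each of the 4 libraries. Within 100 kb of each other lay 2 pairs of called genes, B4galnt1 with Slc26a10 and Islr2 with Stra6, and 449 of 10000 random sets of tested genes matched on expression held as many pairs (one-sided permutation p = 0.0450). B4galnt1 and Slc26a10 overlap by 948 bases and may share reads, and the 100 kb were chosen after the results were seen. The p-value thus does not establish that called genes cluster. Of 122 tested genes within 10 Mb of Pten, 13 had an unadjusted p below 0.05 (10.7%, against 9.83% elsewhere, two-sided Fisher exact p = 0.759), and 0 of the 45 called genes lay on chromosome 19. The median log2 fold change of the 13 other astrocyte markers was 0.22 (95% bootstrap interval -0.04 to 0.49), against 2.43 for Slc1a3. Of 19199 assembled loci, edgeR called 0, with 912 at an unadjusted p below 0.05.

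The gene-level count of Pten was not lower in the libraries labelled PTEN-cKO. By the number of called genes, a swap of 1 WT library with 1 PTEN-cKO library is argued against. The other splits of the 4 libraries called at most 1 gene, against 45 for the split by label. That number depended on single libraries, as given above. The first principal component (38.6% of the variance) separated the replicate numbers, which is a split that such a swap would give. That reads from undeleted exons keep the count up stays open as a candidate explanation. The largest internal exon holds 2.91% of the gene length, and the 95% interval of Pten in PTEN-cKO reaches down to 88.5% of WT. The loss of the reads of that exon alone would thus not show at gene level if the rest of the transcript kept its level. Whether it would keep its level was not tested. Counts per exon and the deleted exons are not given in the sources used here, and deletion in a part of the cells and controls with 1 floxed allele stay open as untested.

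Pericyte and smooth muscle markers were higher in the libraries labelled PTEN-cKO. The median log2 fold change of pericyte markers exceeded that of choroid plexus markers by 1.28 (95% bootstrap interval over genes 0.95 to 1.56), and it did so in all 4 pairs of a PTEN-cKO and a WT library. Pericyte and choroid plexus markers thus did not rise alike. This cannot decide on a lower endothelial share that raises every other cell type. The interval leaves out the spread between libraries, and choroid plexus markers summed to 1750 and 4563 CPM in WT alone. Medians were also above 0 for fibroblast (0.88), leukocyte (1.17), perivascular macrophage (0.75), microglia (0.42), neuron (0.29) and astrocyte markers (0.24). They were below 0 for erythroid (-1.11), oligodendrocyte precursor (-0.30) and oligodendrocyte markers (-0.03). More mural cells in the sort, which was for endothelial cells, may account for the pattern, with Myh11 at 317 ± 93.1 and 609 ± 253 CPM and Myl9 at 259 ± 106 and 484 ± 175 CPM. All 21 mural markers had a log2 fold change above 0 in the fit of all libraries together. Without PTEN-cKO replicate 2 it was 17 of 21, short of the 18 set beforehand. The medians between PTEN-cKO replicate 1 and WT replicate 2 were 0.05 for pericyte and 0.11 for smooth muscle markers. An increase of these transcripts per cell after the loss of PTEN, or in the sorted endothelial cells themselves, was not tested.

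Brain endothelial transporters were lower, while common endothelial markers were not called with all libraries and were called as lower without WT replicate 2 or PTEN-cKO replicate 1 (mean -0.18 and -0.17). Dilution of endothelial RNA by other cells as the only cause is argued against. The median of the transporters lay below that of the 21 other common endothelial markers by 0.38 on the log2 scale (difference -0.38, 95% bootstrap interval over genes -0.53 to -0.22). The interval leaves out the spread between libraries. The sign was the same in all 4 pairs of libraries, which reuse the same 4 libraries and are not independent. A larger share of arterial endothelium in the sort could contribute and stays open. Of 23 arterial markers, 17 lay above 0, short of the 18 that it was taken to need, and Dll4 fell adjusted over the list alone. The 11 that would have excluded it was set after the 17 was seen, so lying above that bound decides nothing. A first bound, fewer than 18 above 0 with at least 1 lower marker past the threshold over the list alone, was met. It would have argued against a larger arterial share. This first bound was replaced because Dll4 is not specific to arteries, so its fall does not exclude a larger arterial share. A change of transporter expression in the endothelium itself with the loss of PTEN was not tested and stays open, since the design does not separate it from a change in the mix of vessel types.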
